A study of Homo sapiens with 6 samples.

How the data were processed

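The series holds 6 samples of HepG2 cells in 2 groups, 3 control and 3 PBLD overexpressed, grouped by their labels. Per the labels, total RNA was extracted with Trizol and purified on columns, labelled with biotin by amplification and hybridised to Illumina bead arrays. The submitters' processing notes name BeadStudio, with no version or role. The authors deposited a value table of 47323 probes per sample on a scale that fits log2 intensity, with each array at a median of 8, and how it was scaled, background-treated or logged is not given in the sources used here. A second deposited table of non-normalized signals was not used here, because its 12 per-sample columns (6 signal and 6 detection columns) carry names that match no sample's labels.

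The plan, made before the data were examined, was to start from the non-normalized signals with limma's neqc and a detection filter. Those columns could not be assigned from their names, and no match by value was used. The deposited log2 values were therefore used as they stand and every probe was tested. These values had been planned only as an alternative, and their choice as the main setting departs from the plan. Normexp and then quantile normalization, without a detection filter, was the plan's fallback for a file without detection p-values. Run here on the deposited values as an alternative, it gave 651 changed genes, 245 higher and 406 lower. The main setting gave 2006, 1164 higher and 842 lower, so the count and the majority direction depend on this choice. The thresholds, gene lists, rule for named genes and most alternatives were also fixed before the data were examined, and 5 alternatives were added after seeing the data.

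Differences were tested per probe with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, PBLD overexpressed minus control, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. All fold changes are on the deposited log2 scale. Each gene was represented by its probe with the highest mean over the 6 arrays. Of the probes, 30113 carry 1 gene symbol, 8 carry several and 17202 carry none in the platform annotation. Probes with several symbols were not named, and those with none are unnamed here. Of 30121 annotated probes, 30074 were matched through their Entrez identifier to RefSeq gene names of the assembly GRCh38.p14, which changed 0 symbols. No genome build is named for the array, so no coordinates are given.

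A background limit was set per array as the 95th percentile of 587 probes for olfactory, taste and vomeronasal receptor and keratin-associated genes, which liver cells do not express, and it ran from 8.06 to 8.09. Where no array of a group was above its limit, the fold is given as a bound, "at least N-fold": the brighter group's mean against the mean of, per array, the higher of the limit and the probe's own value. Of the genes, 10876 were above background on at least 3 arrays, as were 1998 of the changed genes.

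The genes named in the text are PBLD, the 8 largest rises and 8 largest falls among changed genes whose groups do not overlap, up to 4 members per changed list with the smallest p in its direction, and a fixed panel (AFP, ALB, CDH1, VIM, CCND1, CDKN1A, DUSP6, EGR1 and VEGFA, with 1 further member not reported here). Genes with placeholder symbols were left out of the largest rises and falls. Genes outside this rule are marked as chosen after their values were seen.

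The 40 gene lists, with 7 to 33 measured members, were tested with camera (preset correlation 0.01) and adjusted over the lists. Camera with the correlation estimated per list and fry, whose p tests whether a list's genes move one way on balance without comparing them with other genes, were alternatives. Some genes sit in more than 1 list, among them BNIP3, VEGFA, ANGPTL4, PPARGC1A, HPX, AXL, CCN2, THBS1, ACTA2, BIRC5, BAX, GADD45A, AKR1B10, ABCC2, PGK1, GAPDH and PROM1.

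The alternatives were quantile normalization, normexp with offset 50 and then quantile, an intensity trend with robust eBayes, array quality weights, a replicate block, leaving out each array, a 2-fold or 0.01 threshold, averaging a gene's probes and the other set tests. Those added were 75th percentile scaling, cyclic loess and 3 filters on dim probes. The steps were tested on simulated data for PBLD overexpressed minus control over 47323 probes with 200 changed, 50 per fold, and recovered 76% of 1.25-fold changes and 100% of 1.5-fold, 2-fold and 4-fold changes, with 10 false calls among 198. The changed genes were drawn only from those above background on at least 3 arrays, with normal noise independent between probes. Recovery of dimmer genes and false calls under noise shared between genes were not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.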

Results

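Gene expression was measured in HepG2 cells, an established human line derived from a liver tumour that keeps many hepatocyte functions, with and without overexpression of PBLD. PBLD is a protein named for a domain that resembles those of phenazine biosynthesis enzymes. Total RNA from 3 control samples and 3 PBLD overexpressed samples was hybridised to Illumina bead arrays, 1 sample per array, and 47323 probes were measured on each. Every array had a median of 8 on the deposited log2 scale, and the 75th percentiles ran from 8.5 to 8.6. Between 18580 and 19618 probes per array, 39.3% to 41.5%, lay above the background limit set from probes of genes that are silent in liver cells. Pearson's r across probes was 0.995 to 0.996 between arrays of the control group, 0.995 to 0.996 between arrays of the PBLD group and 0.99 to 0.992 between groups, and probes are not independent replicates. Nothing says that the samples of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

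PBLD itself was measured to check the overexpression. The probe ILMN_1789653 rose from 8.09 ± 0.09 in control cells to 12.73 ± 0.11 in PBLD cells (log2, mean ± SD, n = 3 each), a log2 change of 4.64 (SE 0.07, limma adjusted p = 5.29e-16). That is 25-fold on the deposited scale, with 1 of the 3 control arrays above background, and at least 24.4-fold with the controls raised to the background limit. The probe ILMN_2304404 rose from 7.84 ± 0.06 to 12.25 ± 0.10, a log2 change of 4.40 (SE 0.07, limma adjusted p = 5.29e-16), which is at least 18-fold because no control array was above background. The other two probes annotated to PBLD, ILMN_1699684 and ILMN_1760748, were above background on no array, with log2 changes of -0.05 (adjusted p = 0.881) and 0.05 (adjusted p = 0.867). The deposited values are not background-subtracted as far as their range shows, so folds of dim probes are understated, and after normexp background correction the log2 change of ILMN_1789653 was 5.75.

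**Figure D1:**
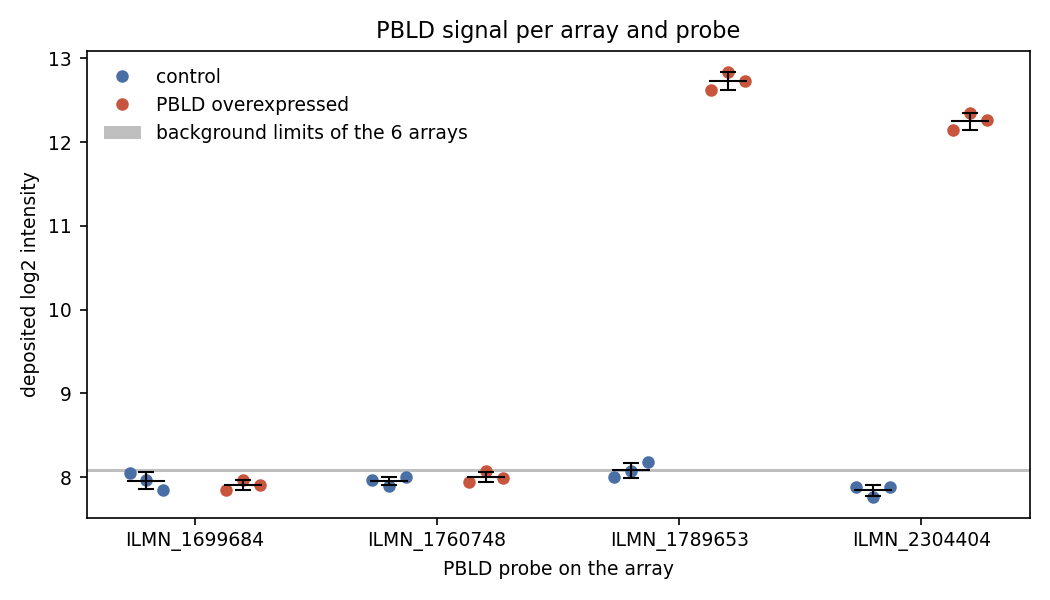
Deposited log2 values (vertical axis) of the 4 PBLD probes (horizontal axis) on the 3 control and 3 PBLD overexpressed arrays, where each point is an array, the black tick is the group mean and the bar is the SD. On ILMN_1789653 the group means are 8.09 and 12.73, while ILMN_1699684 and ILMN_1760748 stay at background in both groups.

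The comparison of PBLD overexpressed with control cells asks which transcripts differ when PBLD is raised. Whether the control cells carried an empty vector is not given in the sources used here, so effects of a vector or its delivery may be part of every difference. In camera with a preset correlation, 7 gene lists passed as higher, among them cell division, protein folding, metal binding and ribosome assembly, and 8 as lower, among them hypoxia, glucose production and secreted plasma protein genes, while 0 passed after adjustment with an estimated correlation (5 at an unadjusted p under 0.05). Beyond PBLD, the largest rises were those of RTL8C, a retrotransposon-derived gene (log2 change 1.82, SE 0.07), the metallothioneins MT1H (1.69, SE 0.11), MT1G (1.57, SE 0.08) and MT1F (1.22, SE 0.08), EDN1, which encodes the vasoconstrictor endothelin-1 (1.5, SE 0.06), BEX1 (1.48, SE 0.06) and HSPA1A, the inducible chaperone HSP70 (1.25, SE 0.09). The largest falls were those of CDH2, which encodes N-cadherin (-2.71, SE 0.07), DUSP1, a phosphatase that switches off MAP kinases (-2.17, SE 0.08), and FMO5, a flavin-containing monooxygenase (-1.93, SE 0.07). They were followed by TNNI2, a skeletal muscle troponin (-1.90, SE 0.07), JUN, a subunit of the AP-1 transcription factor (-1.87, SE 0.08), PROM1, which encodes the stem cell marker CD133 (-1.74, SE 0.07), G6PC1, the glucose-releasing phosphatase of liver (-1.54, SE 0.08), and the immediate early factor EGR1 (-1.5, SE 0.08). By the rule that chose these 16 genes, PBLD included, the 3 PBLD arrays all lie on one side of the 3 control arrays.

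CDH2 went from 11.27 ± 0.12 to 8.56 ± 0.10 (n = 3 each), 6.53-fold lower with a limma adjusted p of 2.52e-12. DUSP1 was 4.50-fold lower (adjusted p = 7.62e-11), FMO5 3.82-fold (5.30e-11 as its adjusted p), JUN 3.67-fold (4.86e-10) and EGR1 2.82-fold (1.39e-08). RTL8C was 3.54-fold higher (adjusted p = 2.83e-10), EDN1 2.84-fold (3.03e-10) and BEX1 2.79-fold (4.54e-10). These folds are for the deposited values, and normexp background correction gave larger log2 changes for CDH2 (-3.38), FMO5 (-2.81), TNNI2 (-2.86), PROM1 (-2.58), RTL8C (2.53) and EDN1 (2.14), which is over 1.5 times the fold in each. The ranking therefore holds only on the deposited scale. FOS, which is not among the genes above, reached -2.59 after normexp, against at most -2.32 for DUSP1 in any setting. A second BEX1 probe rose by 0.37, and a second G6PC1 probe changed by -1.59. TNNI2 was above background on 2 of the 3 PBLD arrays. The MT1 genes are close relatives of one another, as are HSPA1A and HSPA1B, so which member of each family a probe measures is uncertain.

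Across the array, 2006 of 20046 genes changed (10%), of which 1164 rose and 842 fell. The median size of a change was 0.36 on the log2 scale, or 1.28-fold. At least 2-fold changes numbered 50, with 15 higher and 35 lower. At the probe level 2875 of 47323 changed, 1658 higher and 1217 lower. The 2 groups did not overlap in 4685 of all genes (23.4%), against the 10% that chance gives for 3 arrays against 3. They did not overlap in 1989 of the 2006 changed genes either, a share that follows largely from the call itself and is no separate support. Of the 6691 genes with several probes, HNRNPA2B1, an RNA-binding protein named here after its values were seen, was the 1 gene with called probes going both ways (-0.50, 0.29 and -0.38). The split between rises and falls moved with some scalings, being 1290 higher and 1332 lower after quantile normalization and 1177 and 1475 after cyclic loess, but 1481 and 1014 after 75th percentile scaling. Normexp followed by quantile normalization, which changes the background as well, gave 245 higher and 406 lower, 651 in all. The split also moved with single arrays, with 520 genes lower without control replicate 1, 741 higher without control replicate 3 and 775 higher without PBLD replicate 2. A total of 279 called genes, mainly members of the lists below, were followed through the alternatives. Of these, 132 lost their call with normexp and 34 with an intensity trend and robust eBayes. The call was lost by 51, 40 and 32 without control replicates 1, 2 and 3, and by 45, 27 and 24 without PBLD replicates 1, 2 and 3. The sign changed for 0 of them.

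**Figure D2:**
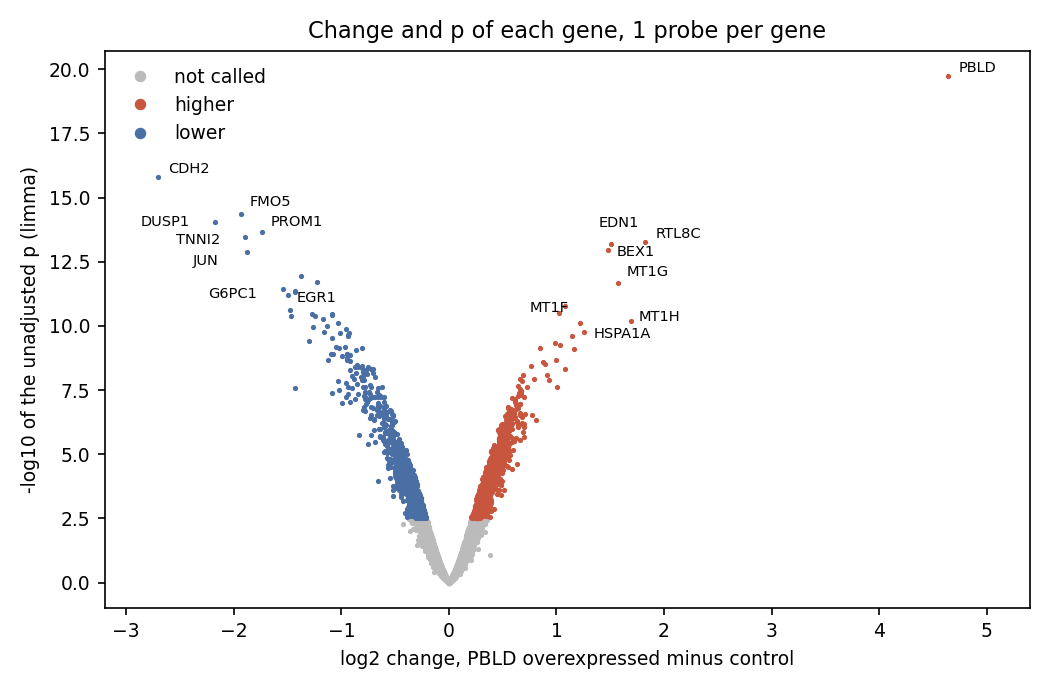
Log2 change of each gene, PBLD overexpressed minus control (horizontal axis), against -log10 of the unadjusted limma p (vertical axis), where each point is a gene represented by 1 probe and colours mark the 1164 genes called higher, the 842 called lower and those not called. PBLD stands apart at 4.64, and CDH2 is the lowest at -2.71.

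**Figure D3:**
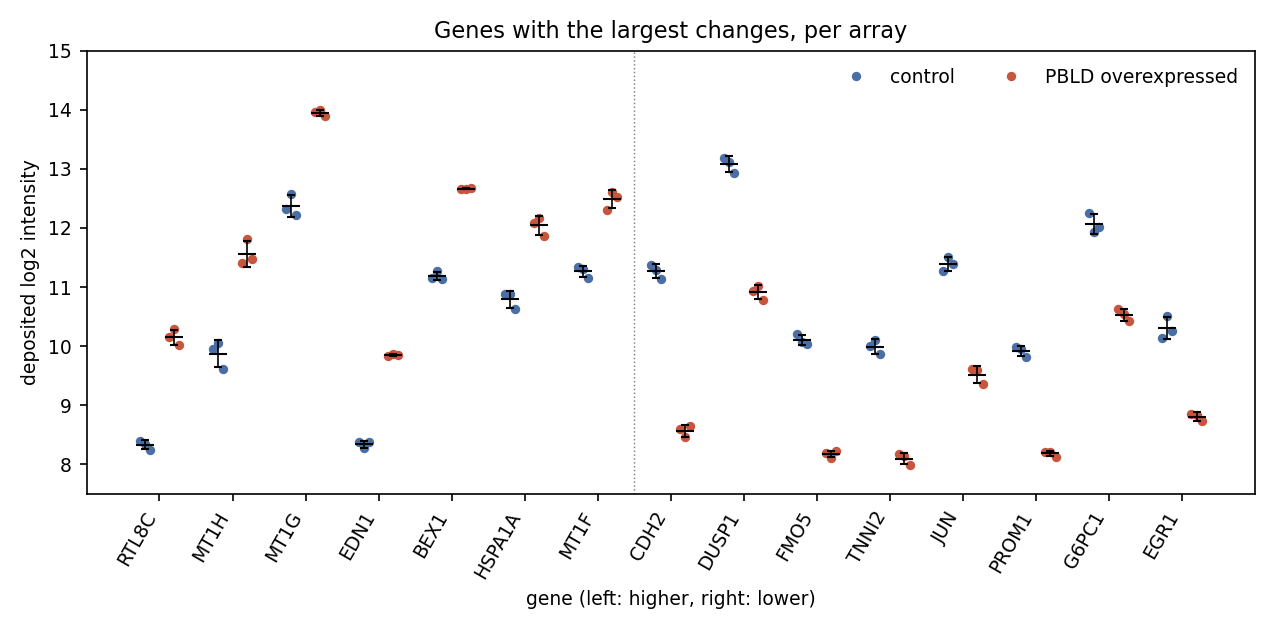
Deposited log2 values (vertical axis) of named genes (horizontal axis) on the 3 control and 3 PBLD overexpressed arrays, where each point is an array, the black tick is the group mean and the bar is the SD. The CDH2 means are 11.27 and 8.56.

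Among 40 gene lists fixed before the data were examined, 15 passed camera at an adjusted p of 0.05 with a preset correlation between genes, 7 of them higher and 8 lower. With the correlation estimated per list, camera called 0 lists after adjustment and 5 at an unadjusted p under 0.05, while fry called 11, of which 9 were among the 15. The counts below use p-values adjusted over all probes, and each is followed by the count adjusted over the list alone. In each list, measured members outside the count did not pass, and only examples of those counted are named.

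Of 30 G2/M and mitosis genes, 26 rose and 4 did not pass (27 rose adjusted over the list alone). The list had a median of 0.47 and a camera adjusted p of 1.21e-26, and the call was lost at an adjusted p = 0.337 with an estimated correlation (alternatives ranged from 1.15e-30 to 0.337). The risers included CENPA, the centromeric histone (0.76), CDC20, an activator of the anaphase-promoting complex (0.67), KIF20A, a kinesin of cytokinesis (0.64), and the mitotic kinase AURKA (0.56). The members that did not pass were MKI67 (0.02), CDC25B (-0.01), BUB1B (0.25) and UBE2C (0.13), named after their values were seen. Of 29 G1/S and DNA replication genes, 20 rose, 1 fell and 8 did not pass (22 rose and 1 fell adjusted over the list alone). Their median was 0.37 and the adjusted p was 2.60e-15, again with an adjusted p = 0.337 with an estimated correlation (5.81e-17 to 0.337 over the alternatives). Those that rose included the replicative helicase subunits MCM7 (0.70) and MCM4 (0.59), cyclin D3 (CCND3, 0.67) and the flap endonuclease FEN1 (0.64). CDK4, the kinase partner of D cyclins, was the 1 member to fall, by either count (-0.75, adjusted p = 2.08e-06), and is named after its value was seen.

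Of 24 CDK inhibitors and p53 targets, 9 rose, 1 fell and 14 did not pass (11 rose and 2 fell adjusted over the list alone). For these targets the median was 0.12 with an adjusted p of 0.000868, with an adjusted p = 0.349 with an estimated correlation and 0.0536 with fry (0.000324 to 0.349 over the alternatives). TIGAR, which restrains glycolysis (0.59), the nuclease AEN (0.48), the AKT repressor PHLDA3 (0.52) and the phosphatase PPM1D (0.45) had the smallest p among the rises, and CDKN1A, which encodes the CDK inhibitor p21, rose by 0.47 (adjusted p = 0.00143). CDKN1B, which encodes the inhibitor p27, fell by 0.73 on the log2 scale (adjusted p = 8.77e-06) and is named after its value was seen. AEN (0.45), PPM1D (0.52) and CDKN1A (0.43) lost their calls after normexp background correction, at log2 changes close to those above.

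Of 25 MYC target and ribosome assembly genes, 15 rose and 10 did not pass (17 rose adjusted over the list alone). The median was 0.31 and the adjusted p 1.48e-11, with an adjusted p = 0.337 with an estimated correlation (1.64e-13 to 0.337 over the alternatives). The genes that rose included ODC1, the first enzyme of polyamine synthesis (0.84), LYAR, a nucleolar protein (0.81), and the ribosome assembly factors BOP1 (0.56) and MRTO4 (0.50). Of the structural genes of the ribosome, 0 of 33 cytosolic ribosomal protein genes passed in limma, where 1 was higher and 2 were lower at an unadjusted p under 0.05, and 0 passed adjusted over the list alone (camera adjusted p = 0.739).

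Of 19 heat shock chaperone genes, 12 rose, 1 fell and 6 did not pass (14 rose and 1 fell adjusted over the list alone). Chaperone genes had a median of 0.36 and an adjusted p of 2.47e-10, with an adjusted p = 0.337 with an estimated correlation (3.18e-12 to 0.337 over the alternatives). HSPA1A (1.25) and HSPA1B (1.03), whose probes may not tell them apart, were joined by HSPH1, a nucleotide exchange factor of HSP70 (0.99), and the co-chaperone DNAJA1 (0.53). HSPB1, a small heat shock protein, went the other way (-0.55, adjusted p = 0.00102) and is named after its value was seen. Of 7 metallothionein genes, 6 rose (7 adjusted over the list alone), MT1X by 0.70 and MT1E by 0.57 beside those above. Their median was 0.70 and the adjusted p 2.47e-12, with an adjusted p = 0.337 with an estimated correlation (1.36e-22 to 0.337). MT1M, above background on no control array, was at least 1.01-fold higher (adjusted p = 0.0361), and MT1E and MT1M are named after their values were seen. The unfolded protein response, which acts in the endoplasmic reticulum, had 7 of 23 genes higher (9 adjusted over the list alone), including SDF2L1 (0.79), CRELD2 (0.68), MANF (0.55) and the co-chaperone DNAJB11 (0.47), and 16 that did not pass. For this list the median was 0.11 and the adjusted p 4.45e-06, with an adjusted p = 0.337 with an estimated correlation (1.97e-06 to 0.337), and DNAJB11 lost its call after normexp.

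Of 30 glycolysis and hypoxia genes, 12 fell and 18 did not pass (15 fell and 1 rose adjusted over the list alone). The list had a median of -0.22 and an adjusted p of 1.27e-10, with an adjusted p = 0.349 with an estimated correlation and 0.0564 with fry (3.48e-13 to 0.349 over the alternatives). The falls included VEGFA, the vascular growth factor (-1.43, SE 0.14), NDRG1 (-1.09), PFKFB4, a regulator of glycolytic flux (-0.90), and the mitophagy receptor BNIP3 (-0.66). VEGFA was 2.69-fold lower (adjusted p = 9.48e-06) with a wide control spread (SD 0.43), and its probes gave -1.43, -1.0 and, at background, 0.03. Of 14 gluconeogenesis genes, 6 fell and 8 did not pass (8 fell adjusted over the list alone). Their median was -0.22 and the adjusted p 5.56e-08, with an adjusted p = 0.337 with an estimated correlation (2.62e-09 to 0.337). Among those that fell were G6PC1 (-1.54), PCK1, the enzyme that commits carbon to glucose synthesis (-0.60), IGFBP1, an insulin-repressed secreted protein (-0.60), and the coactivator PPARGC1A (-0.47). Of 24 genes of fatty acid oxidation and PPARA targets, 7 fell and 17 did not pass (8 fell adjusted over the list alone). Here the median was -0.10 and the adjusted p 2.66e-05, with an adjusted p = 0.337 with an estimated correlation (8.94e-07 to 0.337). These falls included CPT1A, which admits fatty acids to mitochondria (-0.64, but -0.02 with an adjusted p of 0.954 on another expressed probe), the transcription factor CREB3L3 (-0.58) and ANGPTL4, a lipoprotein lipase inhibitor (-0.44, and -0.25 with an adjusted p of 0.0907 on another expressed probe), with PPARGC1A counted in both lists.

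Of 26 plasma protein genes, 11 fell, 1 rose and 14 did not pass (15 fell and 1 rose adjusted over the list alone). With a median of -0.24, they had an adjusted p of 8.45e-09, with an adjusted p = 0.337 with an estimated correlation and 0.0564 with fry (8.85e-10 to 0.337 over the alternatives). The falls included the apolipoproteins APOM (-0.94) and APOC3 (-0.70), the thyroid hormone carrier TTR (-0.59) and AHSG, which encodes fetuin-A (-0.37, not called after normexp). HPX, the haem scavenger hemopexin, rose by 0.99 (adjusted p = 1.36e-06) and is named after its value was seen. Of 30 complement and coagulation genes, 13 fell, 1 rose and 16 did not pass (16 fell and 2 rose adjusted over the list alone). Their median was -0.22 and the adjusted p 2.33e-08, with an adjusted p = 0.349 with an estimated correlation and 0.0634 with fry (8.22e-10 to 0.349). MASP1, a protease of the lectin pathway, fell by 0.80 on its brightest probe and by 0.26 to 0.49 on its other expressed probes, coagulation factor F10 fell by 0.77, the complement inhibitor CFI by 0.47 and SERPINF2, which inhibits plasmin, by 0.49. C6, a component of the membrane attack complex, was the riser (0.25), named after its value was seen.

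Of 22 fetal liver and hepatocellular carcinoma genes, 7 fell, 4 rose and 11 did not pass (8 fell and 4 rose adjusted over the list alone). Fetal genes had a median of -0.11 and an adjusted p of 0.00718, with an adjusted p = 0.681 with an estimated correlation and 0.210 with fry (0.00180 to 0.681 over the alternatives). PROM1 (-1.74), DLK1, a hepatoblast surface protein (-0.84), the growth factor IGF2 (-0.49) and CD24 (-0.46) fell, while BEX1 (1.48), the reductase AKR1B10 (0.60), the transcription factor SOX4 (0.50) and LIN28B, which blocks let-7 maturation (0.32), rose and are named after their values were seen. The fetal list's call also ended with dim probes removed by the stricter limit on all 6 arrays (0.469) or on all arrays of a group (0.0933).

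Of 22 mesenchymal genes, 5 fell, 2 rose and 15 did not pass (5 fell and 3 rose adjusted over the list alone). Mesenchymal genes had a median of -0.02, a mean of -0.18 and an adjusted p of 0.0484, with an adjusted p = 0.349 with an estimated correlation (0.000179 to 0.349 over the alternatives). CDH2, the collagen cross-linking enzyme LOX (-1.16), TAGLN (-0.59), the receptor AXL (-0.49) and fibronectin (FN1, -0.42) fell, whereas thrombospondin (THBS1, 0.91) and ACTA2 (0.38) rose, FN1, THBS1 and ACTA2 being named after their values were seen. The mesenchymal list lost its call without control replicate 2 (0.0525), PBLD replicate 1 (0.0699) or PBLD replicate 2 (0.0508 as adjusted p). It was also lost after quantile normalization (0.0597), normexp (0.0754), cyclic loess (0.0697) and averaging of a gene's probes (0.103).

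Of 15 blood and immune cell markers, 5 of them above background, 2 fell (2 adjusted over the list alone), CD3D (-0.42) and LYZ (-0.31), beside CD14 (-0.23, adjusted p = 0.125) and CD2 (-0.18, adjusted p = 0.165). The blood marker list had a median of -0.04 and an adjusted p of 0.0484, with an adjusted p = 0.337 with an estimated correlation (0.00541 to 0.337), and it lost its call without control replicate 1 (0.0677), control replicate 2 (0.05004), PBLD replicate 1 (0.0699) or PBLD replicate 2 (0.103). Quantile normalization (0.0597), normexp (0.0774), cyclic loess (0.0586), an intensity trend (0.0542) and fry (0.0536 as adjusted p) ended that call too. LYZ was not called without control replicate 1 or 2 or PBLD replicate 1 or 3, where its adjusted p was 0.0982, 0.126, 0.126 and 0.0680, nor after normexp (0.179), within a range of 0.000837 to 0.179 over its alternatives. CD14 passed without control replicate 3 (adjusted p = 0.0196), after quantile normalization (0.0216), after cyclic loess (0.0113) and with the replicate number as a block, within a range of 0.0113 to 0.451.

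**Figure D4:**
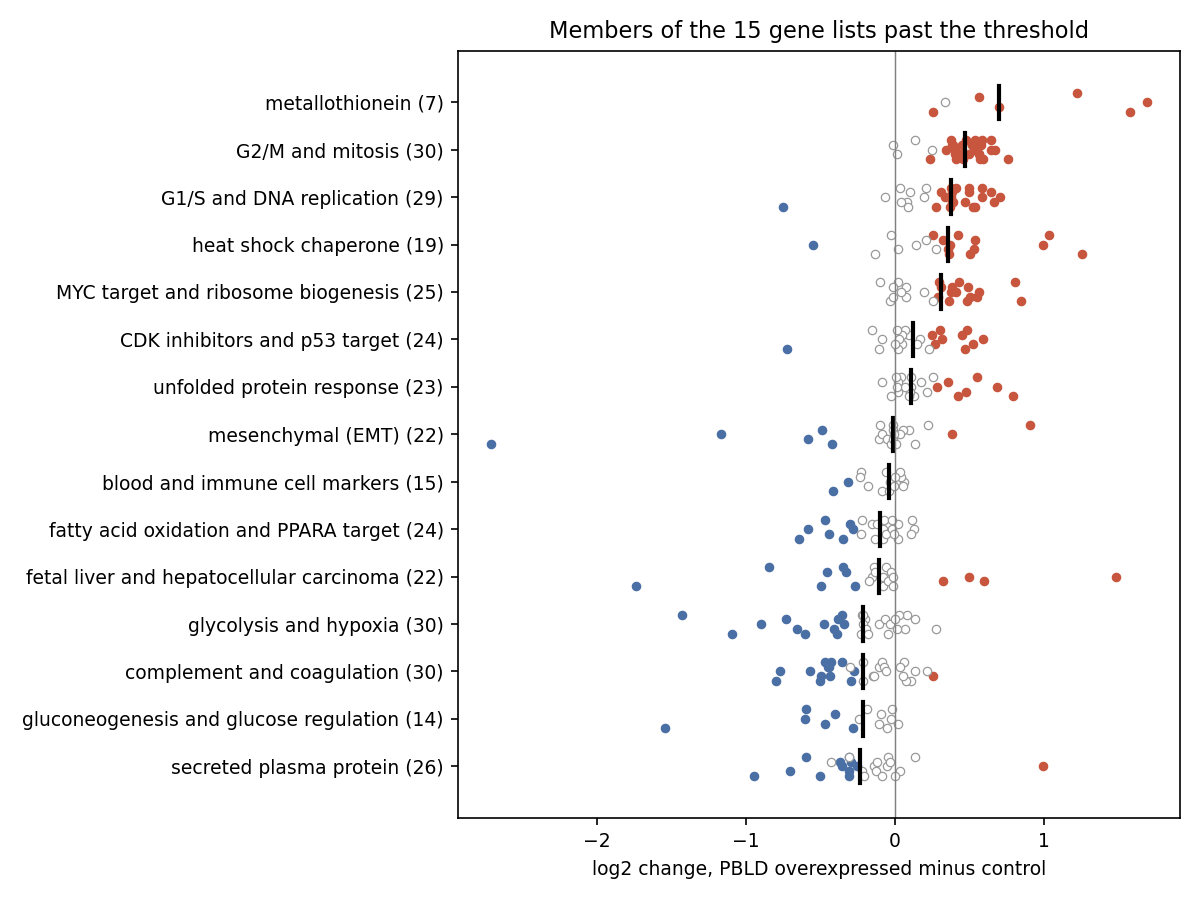
Log2 change, PBLD overexpressed minus control (horizontal axis), of the measured members of the 15 gene lists that passed camera with the preset correlation (vertical axis, number measured in brackets). Each point is a gene, filled if past an adjusted p of 0.05 and open if not, and the black bar is the list's median. The metallothionein median of 0.70 is the highest.

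The remaining 25 lists did not pass camera with the preset correlation, and their members are named here after their values were seen. Of 28 immediate early and MAP kinase genes, 7 rose and 4 fell (11 and 6 adjusted over the list alone, camera adjusted p = 0.770). DUSP1, JUN, EGR1 and FOS, all induced within minutes of growth factor signalling, fell, with FOS at 9.27 in control cells and at background in all PBLD arrays (7.84), at least 2.28-fold lower (adjusted p = 1.04e-08; log2 change -1.43, or -2.59 after normexp). IER3 (1.17), PHLDA1 (0.66), the ERK pathway inhibitors SPRY4 (0.64) and SPRY1 (0.46), FOSL1 (0.35), DUSP5 (0.35) and KLF6 (0.28) rose. Of 23 TGF-beta/SMAD targets, ID3 rose (0.70) while CCN2 (-0.67) and NEDD9 (-0.32) fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.717). Among 19 YAP/TEAD targets, GADD45A rose (0.25) and CCN2, AXL and AJUBA (-0.29) fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.889). Among 23 Wnt targets, the pathway inhibitors DKK4 and NKD1 (0.51) rose with TNFRSF19 (0.36), and DKK1 fell by 0.74 (5 and 1 adjusted over the list alone, camera adjusted p = 0.717). DKK4 was above background on no control array and was at least 1.90-fold higher (adjusted p = 3.37e-08; log2 change 1.08, or 1.98 after normexp).

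Lists of cell death and inflammation genes held changes in both directions. Of 25 pro-apoptotic genes, BAX (0.30), FADD (0.28), TNFRSF10A (0.25) and BID (0.22) rose, while the death ligand TNFSF10 (-1.03) and the mitophagy receptors BNIP3L (-0.81) and BNIP3 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.804). Of 17 anti-apoptotic genes, BIRC5 (0.58) and FAIM (0.33) rose and CFLAR fell by 0.43 (3 and 1 adjusted over the list alone, camera adjusted p = 0.771). Of 25 NF-kB targets, NFKB1 (0.28) and NFKBIE (0.26) rose while SOD2 (-0.39), LTB (at background in all PBLD arrays, at least 1.16-fold lower) and ICAM1 (-0.31) fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.0610). Of 31 interferon-stimulated genes, PARP9 rose (0.26) and ISG20 (-0.46) and IFIT1 (-0.37) fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.0610). Of 19 acute phase genes, the iron hormone HAMP (1.0), HPX, SAA4 (0.50) and ORM2 (0.24) rose, and SERPINA3 (-0.93) and CEBPD (-0.41) fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.725). Of 22 angiogenesis factors, THBS1 and NRP1 (0.27) rose and VEGFA, ANG (-0.52), VEGFB (-0.46), ANGPTL4 and EFNA1 (-0.31) fell (4 and 6 adjusted over the list alone, camera adjusted p = 0.369).

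Metabolic and stress lists outside the 15 also held changed genes, most of these lists in both directions, which camera as a test of 1 direction can miss. Of 30 ATF4 and amino acid response genes, DDIT4 (0.77), WARS1 (0.60), GDF15 (0.55) and DDIT3 (0.33) rose, and STC2 (-0.42), VLDLR (at background in all PBLD arrays, at least 1.18-fold lower), SLC38A2 (-0.35), ASNS (-0.34) and TRIB3 (-0.28) fell (5 and 8 adjusted over the list alone, camera adjusted p = 0.192). Of 25 NRF2 and oxidative stress genes, AKR1C2 (0.62), AKR1B10, GPX2 (0.59), TXNRD1 (0.30) and NQO1 (0.28) rose, and haem oxygenase HMOX1 (-0.61), catalase (CAT, -0.54) and ABCC2 (-0.46) fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.154). Of 20 cholesterol genes, EBP (0.35), IDI1 (0.34), FDPS (0.34) and ACAT2 (0.31) rose and DHCR7 fell by 0.33 (6 and 1 adjusted over the list alone, camera adjusted p = 0.0610). Of 22 fatty acid synthesis genes, the desaturase FADS1 (0.44), ACLY (0.30) and ACACA (0.28) rose (6 and 2 adjusted over the list alone, camera adjusted p = 0.128). Of 30 xenobiotic and bile acid genes, the near-identical glutathione transferases GSTA2 (1.14) and GSTA1 (1.08), which are uncertain as single genes, rose with SLCO1B3 (0.66) and UGT2B7 (0.26). CYP8B1, which sets the balance of bile acids (-0.65), ABCC2, SULT1A1 (-0.38), SULT2A1 (-0.35), ABCB4 (-0.35) and CYP3A5 (-0.25) fell (5 and 6 for this list adjusted over the list alone, camera adjusted p = 0.697). Of 32 oxidative phosphorylation genes, UQCRB rose (0.38; 1 adjusted over the list alone, camera adjusted p = 0.0767).

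Identity and reference lists came last. None of 18 liver transcription factor genes passed in limma, with 1 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.725). Of 20 epithelial junction and keratin genes, KRT8 rose (0.39) and JUP (-0.45) and DSP (-0.34) fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.220). Among 15 replication-dependent histone genes, H2BC12 (-0.86, or -1.56 after normexp) and H2AC18 (-0.39) fell (2 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.943). Of 15 reference genes, PGK1 (-0.60), B2M (-0.45), HPRT1 (-0.39), GAPDH (-0.34) and TFRC (-0.24) fell (5 adjusted over the list alone, camera adjusted p = 0.0784), PGK1 and GAPDH being glycolytic enzymes that sit in the glycolysis list too. Of markers of other cell types, ACTA2 rose among 13 fibroblast markers (1 adjusted over the list alone, camera adjusted p = 0.988) and ESAM (0.56) among 13 endothelial markers (1 adjusted over the list alone, camera adjusted p = 0.454). ANXA4 rose (0.30) and SPP1, which encodes osteopontin, fell (-1.14) among 10 cholangiocyte markers (1 and 1 adjusted over the list alone, camera adjusted p = 0.503), and PROM1 fell among 12 kidney or neural markers (1 adjusted over the list alone, camera adjusted p = 0.0767). Median and mean differed in sign for the pro-apoptotic, MAP kinase, xenobiotic, Wnt, YAP/TEAD, ribosomal protein, histone, fibroblast and cholangiocyte lists. Fry passed the endothelial list (adjusted p = 0.0411) and the kidney or neural list (adjusted p = 0.0131).

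Of the genes named whatever their result, the hepatocyte products AFP (-0.17, adjusted p = 0.426) and ALB (-0.05, adjusted p = 0.902) did not pass, nor did E-cadherin (CDH1, -0.05, adjusted p = 0.877), whereas N-cadherin (CDH2) fell as above. Vimentin (VIM, 0.22, adjusted p = 0.0748), cyclin D1 (CCND1, 0.20, adjusted p = 0.116) and the ERK phosphatase DUSP6 (0.19, adjusted p = 0.132) did not pass either. The group means of AFP and ALB, 15.43 to 15.70, lay close to the array maxima of 15.73 to 16.04. A limit of the signal may therefore hide changes in AFP and ALB, which was not tested. CDKN1A rose and VEGFA and EGR1 fell, with the values given above. VIM passed after quantile normalization (adjusted p = 0.0442), after 75th percentile scaling (0.0436) and with the replicate number as a block (0.0419), within a range of 0.0419 to 0.298 over its alternatives.

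Some of the single genes named for each list passed narrowly and lost their calls when 1 array was left out, with the same sign in every setting. Without PBLD replicate 1, the calls of ABCB4, ACACA, AJUBA, ANXA4, BAX, BID, C6, DHCR7, DUSP5, FADD, FAIM, GADD45A, H2AC18, KLF6, KRT8, LIN28B, LYZ, NFKB1, NQO1, NRP1, ORM2, PARP9, TFRC, TNFRSF10A, TNFRSF19 and UGT2B7 were lost. Without PBLD replicate 2, ACACA, ACAT2, BID, C6, CYP3A5, EBP, FAIM, GADD45A, KLF6, MT1M, NFKB1, NFKBIE, NQO1, ORM2, TNFRSF10A, UGT2B7 and UQCRB did not pass. Without PBLD replicate 3, this held for ABCB4, ACACA, ANXA4, BID, DHCR7, EFNA1, FDPS, GADD45A, GAPDH, LYZ, MT1M, NFKBIE, PARP9 and TFRC. Without control replicate 1, no call was made for ABCB4, ACAT2, AJUBA, ANG, ANXA4, BID, C6, CYP3A5, DHCR7, DUSP5, EFNA1, FADD, FAIM, GADD45A, GAPDH, LYZ, MT1M, NEDD9, NFKB1, NRP1, ORM2, SULT2A1, TFRC, TNFRSF10A, UGT2B7 and UQCRB. Without control replicate 2, the calls that ended were those of ACACA, ANG, BID, C6, CYP3A5, FDPS, GADD45A, GAPDH, ICAM1, KLF6, LIN28B, LYZ, MT1M, NFKBIE, NQO1, NRP1, ORM2, PARP9, SOD2, TFRC, TNFRSF10A, TNFRSF19, TRIB3 and UGT2B7. Without control replicate 3, they were those of ABCB4, ACACA, ACAT2, ANXA4, BAX, BID, C6, CYP3A5, DUSP5, EBP, FAIM, KLF6, KRT8, MT1M, NFKB1, NFKBIE, NQO1, NRP1, ORM2, PARP9, TFRC, TNFRSF10A, TNFRSF19 and UQCRB. Changes of scaling ended calls of named genes too, most often normexp. With normexp the limma adjusted p was 0.110 for SPRY1, 0.0798 for DSP, 0.0689 for B2M, 0.0542 for HPRT1 and 0.0510 for STC2. For SOX4, GPX2 and C6 it was 0.0840, 0.0569 and 0.133. Quantile normalization ended the calls of LIN28B (0.0508) and GADD45A (0.134), and 75th percentile scaling that of BID (0.0568). The log2 change over all alternatives ranged from 0.19 to 0.31 for BID, from 0.19 to 0.38 for TNFRSF10A, from 0.23 to 0.36 for BAX, from 0.23 to 0.32 for FADD and from 0.19 to 0.42 for C6.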

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

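The added settings, which were 75th percentile scaling, cyclic loess and 3 filters on dim probes, were chosen only after the data were seen. PBLD kept its direction and call in every setting run, at 5.75 after normexp and from 4.59 to 4.69 when 1 array was left out. Normexp reduced the changed probes to 937 and the changed genes to 651 (245 higher, 406 lower), 644 of them shared with the 2006, and the cause was not tested. Genes lower numbered 1332 after quantile normalization and 1475 after cyclic loess, and the cause was not tested. A 2-fold limit left 50 genes (15 higher, 35 lower) and an adjusted p limit of 0.01 left 1171 (638 higher, 533 lower), by their construction. Camera with an estimated correlation called 0 lists in either direction (0 higher, 0 lower; 5 at an unadjusted p under 0.05), and fry called 4 lower. Leaving out 1 array at a time, which leaves fewer samples, gave 1404 to 1950 genes (741 to 1293 higher, 520 to 989 lower), 1985 to 2762 probes and 13 to 18 lists (7 to 9 higher, 6 to 11 lower). ALB, which was not called, turned to 0.036 after quantile normalization and 0.037 after normexp, and ran from -0.14 to 0.015 over left-out arrays (0.015 without control replicate 2). CDH1, also not called, ran from -0.11 to 0.015 (0.015 without control replicate 1). The cause was not tested. Of 279 called genes followed, 145 kept call and direction in every setting, 134 lost the call in at least 1 setting, 132 of them with normexp, and 0 changed sign. No scaling moved the median of all genes by more than 0.1, but most probes lie in the background, so that median can hardly move. Over genes above background on at least 3 arrays it was 0.024 in the main setting, with 58.0% of changed genes higher. It was 0.0086 (49.2%) after quantile normalization, -0.0010 (44.4%) after cyclic loess and 0.028 (59.4%) after 75th percentile scaling. After normexp it was 0.013 (37.6%). Without control replicate 3 it was -0.0031 (42.8%) and without PBLD replicate 3 0.046 (66.3%).

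The replicate numbers did not meet the limit set for pairing, since over all probes the correlations of same-numbered deviations were 0.039, 0.142 and 0.186 and not all above 0.1, and control replicate 1 correlated best with PBLD replicate 2 (0.070). Over probes above background on at least 3 arrays they were 0.109, 0.077 and 0.056, again not all above 0.1, but there every array correlated best with its own number, a hint from the data and not the design. With the replicate number as a block, 2720 genes changed (1581 higher, 1139 lower), the 2006 among them, with 3953 probes, 16 lists (7 higher, 9 lower) and PBLD at 4.64, and VIM (0.0419 as adjusted p) and CD14 (0.0278) passed. The settings not run are the neqc background with median scaling or cyclic loess, both detection p filters and the slide as a block, which need the unassigned columns or a slide number. Signal over background limits the dim genes, whose folds are understated.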

Other observations

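The genes of these opening paragraphs and the tests of the gene count over splits, culture density, shared probes, handling and the PBLD probes were chosen only after the result was seen. Single genes outside the lists, and HAMP from the acute phase list, are given here as values. HAMP, described above, encodes the hormone hepcidin that blocks iron export and was 2.01-fold higher, while SLC40A1, the iron exporter that hepcidin acts on, fell by 1.08 on the log2 scale (SE 0.09), CP, a copper enzyme that oxidises iron, fell by 0.94 (SE 0.07) and LEAP2, a liver-secreted peptide, fell by 0.93 (SE 0.09). The limma adjusted p was 8.57e-07 for SLC40A1, 2.27e-07 for CP and 8.77e-06 for LEAP2. MTTP, which loads lipid onto apolipoprotein B, fell by 0.74 and APOA5, a regulator of plasma triglyceride, by 0.79. TFPI, the inhibitor of tissue factor, fell by 0.94.

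Among regulators, HIF1A, the oxygen-sensitive transcription factor, fell by 0.99 (SE 0.11, limma adjusted p = 2.47e-05), the kinase PIM1 by 0.95, MAP2K1, which encodes the ERK kinase MEK1, by 0.94 and DEPP1 by 1.47. CYP2J2, an epoxygenase, fell by 1.37 and IGFBP7 by 1.28 (-2.06 and -1.88 after normexp). UHRF1, which maintains DNA methylation through replication, rose by 0.70 and HSPA9, the mitochondrial HSP70, by 0.69. HSPA6, an HSP70 that is nearly silent without stress, was above background on no control array (7.99) and at 9.02 in PBLD cells, at least 1.92-fold higher (log2 change 1.02, or 1.82 after normexp).

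The changes were set against other splits of the 6 arrays into 3 and 3. Only 1 of the 10 splits, the real one, gave 2006 genes, and the highest other gave 0 in limma after adjustment, with 480 to 1683 genes in the others and 4352 in the real split at an unadjusted p under 0.05. For gene lists, 1 of 10 splits gave as many as the real 15, and the highest other gave 12. The splits are too few for a share under 0.05. Every other split keeps part of the real difference, because it mixes the groups unevenly.

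In camera with a preset correlation, the G2/M list passed as higher and the glycolysis and hypoxia and plasma protein lists as lower, calls that were lost at an adjusted p = 0.337, 0.349 and 0.337 with an estimated correlation (alternatives from 1.15e-30, 3.48e-13 and 8.85e-10 up to those values), and for the last 2 also with fry (0.0564 each as adjusted p). Scaling to a median that lies in the background was examined as a cause with quantile normalization and cyclic loess. Their medians were 0.43 and 0.41 for G2/M genes, -0.23 and -0.25 for glycolysis and hypoxia genes, and -0.26 under both for plasma protein genes. Scaling to the 75th percentile gave 0.47, -0.21 and -0.23, against 0.47, -0.22 and -0.24 on the deposited scale. It moved the median of all genes only from 0.0088 to 0.0129. Over genes above background on at least 3 arrays, the median moved only from 0.024 to 0.0086 (quantile), -0.0010 (cyclic loess) and 0.028 (75th percentile). Shifts so small could hardly undo list medians of that size, so these scalings leave this cause undecided. They show only that the list medians depend little on the choice among them. Less dense or fresher PBLD cultures at harvest may also give such a pattern. The YAP/TEAD targets, which respond to density, had a camera p of 0.845, which leaves that open because a p that misses the threshold does not show that nothing differed. An effect of PBLD stays open beside these.

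Chaperone and metallothionein lists passed as higher, but each at an adjusted p = 0.337 with an estimated correlation (alternatives from 3.18e-12 and 1.36e-22 up to 0.337), while DUSP1, JUN, FOS and EGR1 fell. Probes shared within the HSPA1A, HSPA1B and HSP90A families are argued against only as the sole source of the heat shock rise. Of the 15 members outside those families, 9 rose and 1 fell, by a rule set after the values were seen. That count does not show which of HSPA1A and HSPA1B a probe measures. Shared probes stay open for metallothioneins, where log2 changes spread over a range of 1.35. An acute handling response in the control cultures stays open: 0 of the 6 other immediate early genes above background fell in limma (0 at an unadjusted p under 0.05) and IER3 rose in every setting, against the direction it needs, but the others were not called in every setting, and KLF6 stayed higher, by 0.21 to 0.34, though its call was lost with normexp, an intensity trend, or without control replicate 2 or 3 or PBLD replicate 1 or 2. A hypothesis that chaperones are part of a wider response was tested on 35 proteasome genes. They were picked only by their PSMA, PSMB, PSMC or PSMD symbols, so not all need be subunits of the proteasome in these cells. Of them 12 rose, with a median of 0.23 and a camera p of 8.13e-13, or p = 0.0988 with an estimated correlation. PSMD14 (0.89), PSMD2 (0.61), PSMD1 (0.47) and PSMC2 (0.42), named after their values were seen, were among the risers, with PSMD1 and PSMC2 not called after normexp, which is consistent with that hypothesis only as far as the preset correlation holds.

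Of the 4 PBLD probes, 2 were above background on no array although the others rose. By annotation, ILMN_1760748 is assigned to the same transcript as the probes that rose, and ILMN_1699684 to another PBLD transcript. A candidate explanation is that the overexpressed transcript lacks the sequence of those probes, which cannot be told apart from probes that do not work, since neither probe positions nor the construct are given in the sources used here.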
